A study of Rattus norvegicus with 8 samples.

How the data were processed

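Gene expression was measured in thigh skeletal muscle of 8 Han Wistar rats, 4 fed compound 197 at 150 ppm for 28 days and 4 controls. Per the labels' protocols, muscle was ground in liquid nitrogen, total RNA was extracted with a column kit for fibrous tissue and treated with DNase, and biotinylated cRNA was made with a TotalPrep kit. The arrays were 1-colour Illumina rat expression beadchips with 22523 probes. The authors deposited a table of non-normalized intensity values and a table of normalized intensity values, per the file headers and names. Each deposited table also gives a detection p-value per probe and array, per the file headers. The scanner software, the detection method and the normalization method are not given in the sources used here.

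The values themselves show more about the deposited normalized table. All 8 of its columns hold the same sorted values, the ranks of each non-normalized column are kept, and the scale is linear with no centring, which is what quantile normalization gives. The shared values are not the mean of these 8 arrays: the mean sorted non-normalized value was 0.955 times the shared value at the median. Which arrays entered that step is not given in the sources used here. The series matrix, whose columns all have a median of 104, held the values of the normalized table in every cell, and the detection p-values of both tables were equal in every cell. The tables hold no column of any sample outside the 8.

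The analysis started from the non-normalized intensities. Background was corrected with limma's neqc, which inferred the background from the detection p-values (offset 16), followed by quantile normalization and log2. A probe was tested if its detection p was under 0.05 on at least 4 of the 8 arrays, which 9873 probes passed. Probes were named through the platform annotation supplied with the series matrix, where 13793 probes have 1 gene symbol, 0 have several and 8730 are not listed. Symbols were brought up to date through Entrez gene numbers with a RefSeq table of the GRCr8 assembly, used for names alone. By number, 13752 probes matched, and the others kept their symbol. Each gene was represented by its probe with the highest mean level among those passing, which gave 7162 genes from 7301 named probes. 131 genes had 2 or more tested probes.

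Groups were compared with limma (lmFit and eBayes) in R, with Benjamini-Hochberg adjustment over the genes tested and a threshold of adjusted p under 0.05. Versions were limma 3.58.1 and R 4.3.3, and figures were drawn with matplotlib 3.10.9. No p-value is adjusted for cage, slide or scan, which the sources used here do not give. Before the data were examined, 44 gene lists were fixed for mitochondria, stress responses, muscle fibres, metabolism and cell types. Lists with at least 5 tested members, 41 in number, were tested as sets with limma's camera at a correlation of 0.01, and also with an estimated correlation and with fry. A list symbol was matched to a gene through its current symbol, or through a synonym carried by 1 gene. Genes named in the text followed a rule fixed at the same time: the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap. Symbols that are only locus numbers were left out. From each list it took up to 4 passing members with the smallest adjusted p, or up to 2 members with the largest change where none passed. Where a probe was above background on no array of a group, the change is given as a lower bound.

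The gene test was tested on simulated data for 7162 genes with the real means and spreads, in which 200 genes were changed. It recovered 43.3% of changes of 0.585, 71.6% of changes of 1 and 97.0% of changes of 2 on the log2 scale, and 5.37% of its calls were false. The set test found a list shifted by -0.5 and called 0 other lists. Each simulated gene was drawn on its own, so neither result shows how the tests behave where genes vary together. The alternatives, most of them fixed before the data were examined, changed the background correction, the normalization, the source of the values, the filter, the summary of probes, the variance model, the threshold and the arrays included. A block for the slide could not be fitted, because no slide is named. Pairs of probes for 1 gene, the shift to the median change, centring and camera on ranks were added after the data were seen. Comparisons of a single value used exact permutation tests, and correlations across genes used 100000 permutations.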

Results

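Total RNA from the thigh muscle of Han Wistar rats, an outbred laboratory stock, was measured on Illumina rat beadchips, arrays on which each gene is read by short probes attached to beads. Compound 197, known here only by that code and placed by the labels among sulfonyl isoxazolines, was given in the feed at 150 ppm for 28 days to 4 rats, and 4 control rats received standard feed. The title of the series places the comparison in the study of mitochondrial toxicity in skeletal muscle. Each rat gave 1 array, and each array read 22523 probes. Between 8310 and 9507 probes were above background on a control array, against 9743 to 10498 on a compound 197 array. The means were 8988 ± 498 and 10109 ± 328 (SD, n = 4 each). This difference had an exact permutation p of 0.0286 (two-sided), the smallest that 4 against 4 can give. The lowest raw signal was also apart, at 51.1 to 55.5 on the compound 197 arrays and 59.3 to 61.6 on the controls. The floor of the arrays thus differed between the groups, so the count of detected probes need not reflect the muscle. Across the genes tested, levels correlated between arrays with r from 0.956 to 0.987 within a group and from 0.914 to 0.947 between the groups.

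Muscle of the rats fed compound 197 differed from control muscle at 2696 of 7162 genes, of which 931 were higher and 1765 lower. Without compound 197 replicate 4 the count was 1780, with 1144 lower, the lowest on leaving out 1 array. Part of that drop comes from the detection filter, since 2491 of the 2696 genes were still tested. The rises were the larger changes. Klhl41, a kelch-family protein of the sarcomere, rose from 6.99 ± 0.19 to 11.96 ± 0.081 log2 intensity (SD, n = 4 each), which is 31.3-fold. By fitted change, also for genes whose probe was above background on no control array, 171 genes rose by at least 4-fold. Falls of that size numbered 7, and the largest was that of Fndc7, 4.50-fold. Sizes depend on the background correction, and without it 86 genes rose and 0 fell by at least 4-fold. Of the changed genes, 1386 differed by at least 1.5-fold, 719 of them higher and 667 lower. Of 44 fixed gene lists, 31 held genes that rose beside genes that fell with quantile normalization. With median scaling most of those falls lay above 0, and 146 list genes were called higher and 4 lower. With cyclic loess 117 list genes were called higher and 40 lower.

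The balance of rises and falls depended on the scaling between arrays. With lower bounds in place of fitted changes for undetected probes, rises stay at or above 0 and so could not move the median change of all genes. With quantile normalization the median change of all genes tested was -0.20 with or without these bounds. That median was 0.31 with median scaling, where 1379 genes were higher and 111 lower, and -0.03 with cyclic loess, where 1148 were higher and 529 lower. Of the 1765 falls, 1063 lay above 0 with median scaling and 1 with cyclic loess, which still called 529 of them lower. On an array 36.9 to 46.6% of probes were above background, so undetected probes set the median used in median scaling. Both scalings moved the median change upward. Relative to the median change, a comparison added after the data were seen, 1186 genes were higher and 497 lower. Changes below are log2 values ± SE with quantile normalization, from limma on 4 arrays per group. Counts relative to the median change and with median scaling are given beside each list. On leaving out 1 array, the count of a list is given only where it differs from the full count by more than 1.5 times. Smaller shifts are not listed.

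**Figure D1:**
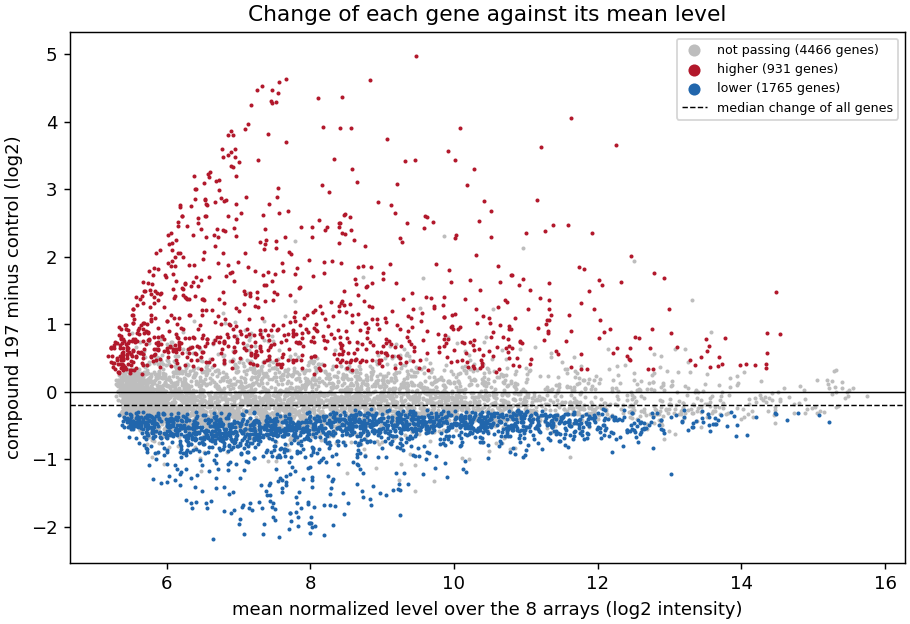
Each point is 1 of the 7162 genes tested, with its mean normalized level over the 8 arrays (log2 intensity) on the horizontal axis and the log2 change, compound 197 minus control, on the vertical axis. The 931 genes called higher reach 4.97, and the dashed line marks the median change of -0.20, which is above 0 with median scaling.

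The 12 largest rises were taken, by rule, from genes with all 4 compound 197 arrays above all 4 control arrays. Besides Klhl41 they held Nop53 and Eif3m, which act in ribosome assembly and translation initiation, Rpl30, a ribosomal protein, and Mrpl1 and Gadd45gip1 of the mitochondrial ribosome. The others were Zfp36l1, a zinc finger protein that promotes mRNA decay, Eloc (elongin C), Snx5, a sorting nexin, Nfib, a transcription factor, Myh2, the myosin heavy chain of type IIa fibres, and Ctsd, a lysosomal protease. Klhl41 rose by 4.97 ± 0.12 (adjusted p = 2.4e-08), Nop53 by 4.63 ± 0.11 and Myh2 by 4.36 ± 0.33 (adjusted p = 1.9e-05). The probes of Zfp36l1, Eloc, Mrpl1 and Gadd45gip1 were above background on no control array, and their rises were at least 20.3-fold, 16.8-fold, 15.7-fold and 16.97-fold. These bounds set the compound 197 mean against the higher of the lowest signal above background and the probe's own signal on each control array. They hold with the background correction used here. Without one, the same bounds were 8.91-fold, 7.50-fold, 7.06-fold and 7.57-fold, the 12 rises ran from 3.05 to 4.34 in place of 4.29 to 4.97, and the bounds of all 15 genes given as such here were 0.44 to 0.97 times as large. Probes above background on only some control arrays were those of Nop53, Snx5, Nfib and Ctsd (1 array each), Rpl30 (2) and Eif3m (3), so control levels there lie partly at background. Of all 931 genes called higher, 201 had a probe above background on no control array, while 7 of the genes called lower had one above background on no compound 197 array. Rpl30 rose by 4.61 ± 1.05 (adjusted p = 0.00988), with an SD of 1.80 among the compound 197 arrays and 1.80 among the controls.

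The 12 largest falls were smaller, from -1.96 for Pafah2, a phospholipase, to -2.17 for Fndc7, and all 12 stayed below 0 with each scaling. They included Ttyh3, Slc24a4 and Galnt13, which encode a chloride channel, a calcium and potassium exchanger and an enzyme of protein glycosylation. Ctla4, an inhibitory receptor of T cells, fell by 2.10 ± 0.32 (adjusted p = 0.00146), and Ccr7, a chemokine receptor of lymphocytes, fell by 1.99 ± 0.28 (adjusted p = 0.00107). The olfactory receptor genes Or14j5, Or8b8 and Or5aq7b fell by 2.08 ± 0.33, 2.03 ± 0.31 and 2.00 ± 0.32, and the vomeronasal receptor gene Vom2r59 fell by 1.98 ± 0.32. Ms4a8 completed the group. The 119 genes that fell by 1.2 or more varied together within the groups, with a mean pairwise correlation of 0.815 between their deviations from the group means. Among them are Chrne, Chrnd, Atf3 and Cdh19, which are given below with their lists.

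**Figure D2:**
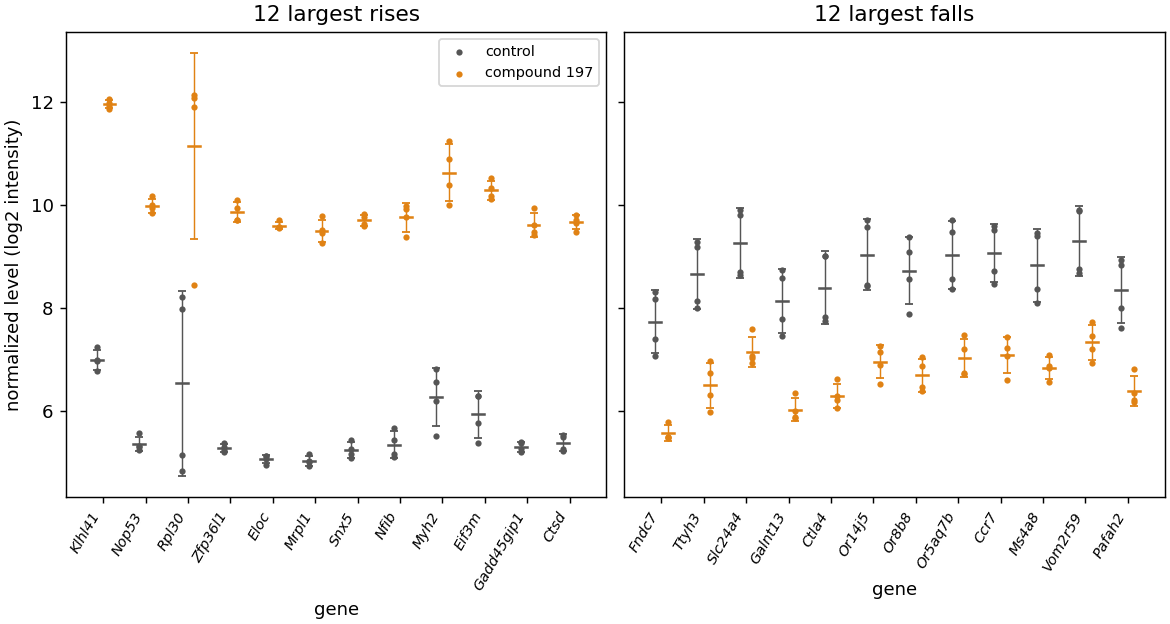
Normalized level (log2 intensity) of the 12 genes with the largest rise and the 12 with the largest fall, with a point per array, a bar at the group mean and whiskers of 1 SD (n = 4 per group). Control points of Klhl41 lie near 6.99 and compound 197 points near 11.96, and the genes were chosen among those with the groups apart.

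For 124 genes, 2 probes passed the filter, 118 of them designed to 1 transcript record, which allowed the change to be measured a second time in the same rats. The log2 changes of the paired probes had a Pearson r of 0.056 (permutation p = 0.529) and a Spearman rho of 0.062 (permutation p = 0.494) across genes, which are not independent replicates. Both probes passed the test for 17 genes, in the same direction for 8 and in opposite directions for 9, and exactly 1 passed for 66. Of 23 probes that rose by 1.5 or more, 2 had a partner that did so, and the median change of the partners was -0.22. Those 2 are the probes of 1 gene, Ppid, each counted as the partner of the other. Nexn, a protein of the sarcomeric Z-disc, chosen as an example after its values were seen, had changes of 2.88 and -0.14. Both of its probes were above background on all 8 arrays, but they were designed to different transcript records. Kiaa1191, picked in the same way, had changes of 3.45 and -0.72 on probes designed to 1 record. These too were above background on all 8 arrays. Ppid, a cyclophilin, rose on both probes, by 1.81 on the brighter, while the dimmer was above background on no control array. Of the genes in the fixed lists, 9 have 2 tested probes, and the brighter, used for the lists, passed for 0 of them. The dimmer passed for 5, higher for Cav1, Gstp1 and Loxl1 and lower for Psmb10 and Tie1. In the lists below, a gene said to rise or fall is read by its brightest probe alone. No such call is backed by the second of 2 tested probes. The many-fold rises there are therefore rises of a probe and may not hold for the whole transcript.

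**Figure D3:**
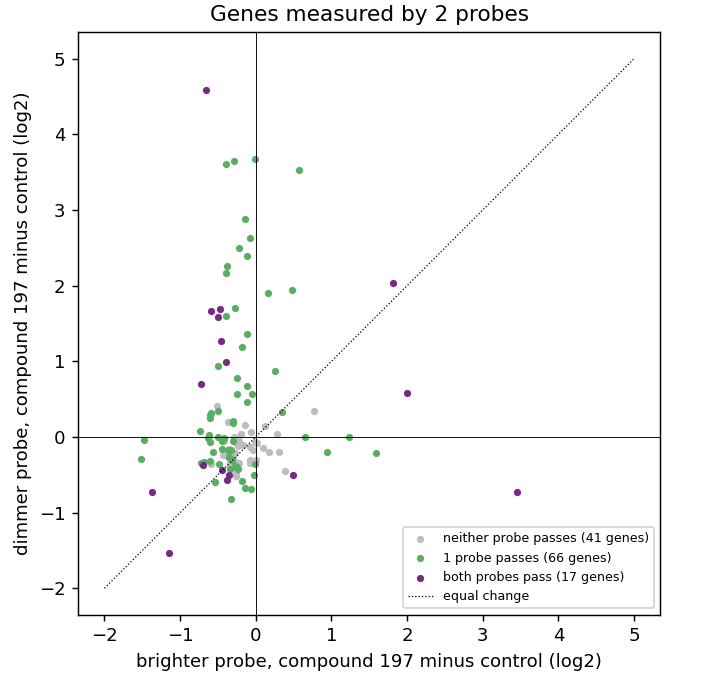
Log2 change, compound 197 minus control, of the brighter (horizontal axis) and the dimmer (vertical axis) probe of the 124 genes with 2 tested probes, coloured by how many of the probes passed the test. Few points follow the dotted line of equal change, and r is 0.056.

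Some transcripts of the respiratory chain were called lower with quantile normalization, but none with median scaling. Cyclic loess called 1 lower in complex I, 1 in complex IV and 1 in ATP synthase. For complex I, the entry point of electrons from NADH, of 27 tested, 3 rose, 7 fell and 17 did not pass (3 higher and 7 lower adjusted over the list alone, 4 and 1 relative to the median change, 5 and 0 with median scaling), and 6 of the falls lay above 0 with median scaling. Its subunit genes rose for Ndufs5 by 2.47 ± 0.17 and Ndufb3 by 0.67 ± 0.11, whereas Ndufa6 fell by 0.66 ± 0.11 and Ndufb8 fell by 0.43 ± 0.10. For complexes II and III, of 9 tested, 0 rose, 0 fell and 9 did not pass (0 higher and 0 lower adjusted over the list alone, 1 and 0 relative to the median change, 1 and 0 with median scaling). Sdha had a change of 0.38 ± 0.16 with an adjusted p of 0.0912. Uqcrfs1 had a change of -0.34 ± 0.14 with an adjusted p of 0.0776. For complex IV, cytochrome oxidase, of 12 tested, 4 rose, 3 fell and 5 did not pass (4 higher and 3 lower adjusted over the list alone, 4 and 1 relative to the median change, 5 and 0 with median scaling), and 2 of the falls lay above 0 with median scaling. Here the rises included Cox6c by 2.61 ± 0.13, Sco1 by at least 1.73-fold and Cox5a by 0.42 ± 0.10. Cox17 fell by 0.59 ± 0.088. For ATP synthase, of 12 tested, 1 rose, 5 fell and 6 did not pass (2 higher and 5 lower adjusted over the list alone, 2 and 2 relative to the median change, 1 and 0 with median scaling), and 3 of the falls lay above 0 with median scaling. Falls were measured for Atp5f1c by 0.63 ± 0.12, Atp5mc2 by 0.45 ± 0.10 and Atp5pd by 0.65 ± 0.14, and a rise for Atp5pf by 0.52 ± 0.14. The probe of Cox6c was above background on 2 of the 4 control arrays. Leaving out 1 array at a time changed these counts and calls, with adjusted p in brackets. Complex I had 3 falls without compound 197 replicate 1 or 4, 4 falls without compound 197 replicate 3 and 12 falls without control replicate 2. Complexes II and III had 5 falls without control replicate 2. Complex IV had 2 rises without compound 197 replicate 1 (1 no longer tested). ATP synthase had 0 rises without compound 197 replicate 1 and 3 falls without control replicate 1, 3 or 4 or compound 197 replicate 1, 2, 3 or 4. Uqcrfs1 passed without control replicate 2 (0.0469). Atp5pf did not pass without compound 197 replicate 1 (0.0558).

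In the tricarboxylic acid cycle and pyruvate dehydrogenase list, of 20 tested, 5 rose, 6 fell and 9 did not pass (6 higher and 7 lower adjusted over the list alone, 6 and 2 relative to the median change, 7 and 0 with median scaling), and 4 of the falls lay above 0 with median scaling. Mpc1, a subunit of the mitochondrial pyruvate carrier, rose by 3.90 ± 0.19 (adjusted p = 1.1e-06) and Mdh1 by 1.69 ± 0.23. Falls were found for Idh2 and the citrate synthase gene Cs (Idh2 by 0.73 ± 0.13 and Cs by 0.66 ± 0.13). Among genes of mitochondrial fatty acid oxidation, of 20 tested, 5 rose, 2 fell and 13 did not pass (5 higher and 2 lower adjusted over the list alone, 5 and 1 relative to the median change, 6 and 0 with median scaling), and no fall lay above 0 with median scaling. The long-chain acyl-CoA synthetase gene Acsl1 rose by 3.44 ± 0.20, Eci2 by 2.40 ± 0.19, Etfa by 2.42 ± 0.23 and Eci1 by 1.23 ± 0.11. In the list of PPAR target genes, of 16 tested, 1 rose, 2 fell and 13 did not pass (1 higher and 0 lower adjusted over the list alone, 1 and 0 relative to the median change, 2 and 0 with median scaling), and 1 of the falls lay above 0 with median scaling. The fatty acid transporter gene Cd36 rose by 1.36 ± 0.30, and the falls were Pdk4 by 0.44 ± 0.14 and Plin5 by 0.89 ± 0.29. These counts and calls changed on leaving out 1 array at a time, with adjusted p in brackets. The tricarboxylic acid cycle list had 3 falls without control replicate 3 or compound 197 replicate 3 or 4. Fatty acid oxidation had 1 fall without control replicate 1, 3 or 4 or compound 197 replicate 2, 3 or 4 and 7 falls without control replicate 2. The PPAR list had 0 falls without control replicate 3 or compound 197 replicate 1, 2 or 4. Pdk4 did not pass without control replicate 2 (0.0580), 3 (0.0703) or 4 (0.0736) or compound 197 replicate 1 (0.0820), 2 (0.0728) or 4 (0.0849). Plin5 did not pass without control replicate 1 (0.0850) or 3 (0.0941) or compound 197 replicate 1 (0.0502), 2 (0.0793), 3 (0.0804) or 4 (0.106).

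For regulators of mitochondrial biogenesis, of 16 tested, 2 rose, 6 fell and 8 did not pass (2 higher and 6 lower adjusted over the list alone, 2 and 4 relative to the median change, 3 and 0 with median scaling), and 3 of the falls lay above 0 with median scaling. The coactivator gene Ppargc1a rose by 1.88 ± 0.20, with its probe above background on 1 control array. Gabpa fell by 0.83 ± 0.12, Sirt3 by 0.59 ± 0.093 and Polrmt by 0.58 ± 0.10. For mitochondrial dynamics and mitophagy, of 13 tested, 4 rose, 6 fell and 3 did not pass (4 higher and 6 lower adjusted over the list alone, 4 and 1 relative to the median change, 4 and 0 with median scaling), and 6 of the falls lay above 0 with median scaling. Rises were found for Opa1 by at least 2.19-fold, Mfn1 by 0.84 ± 0.14 and Phb2 by 0.65 ± 0.10. Fis1 fell by 0.56 ± 0.092. In the mitochondrial ribosome, of 31 tested, 4 rose, 15 fell and 12 did not pass (4 higher and 16 lower adjusted over the list alone, 4 and 7 relative to the median change, 5 and 0 with median scaling), and 9 of the falls lay above 0 with median scaling. Mrpl1 and Mrpl41 rose by at least 15.7-fold and 9.87-fold. Mrpl37 fell by 0.68 ± 0.089 and Mrps14 by 0.74 ± 0.10. Mitochondrial chaperones, proteases and import factors gave this result: of 18 tested, 4 rose, 5 fell and 9 did not pass (4 higher and 6 lower adjusted over the list alone, 5 and 0 relative to the median change, 5 and 0 with median scaling), and 5 of the falls lay above 0 with median scaling. Rises were measured for Trap1 by 1.04 ± 0.13, Tomm20 by 0.90 ± 0.10 and Hspd1 by 0.81 ± 0.14 and a fall for Timm23 by 0.42 ± 0.10. On leaving out 1 array at a time, these counts and calls changed, with adjusted p in brackets. Biogenesis regulators had 1 rise without control replicate 1 or 3 or compound 197 replicate 1, 3 or 4. The mitochondrial ribosome had 1 rise without compound 197 replicate 1, 2, 3 or 4 (3 no longer tested). The chaperone list had 2 falls without control replicate 1 or 4 or compound 197 replicate 1, 2 or 4 and 3 falls without control replicate 2 or 3 or compound 197 replicate 3.

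Stress response lists held genes called lower with quantile normalization, but none with median scaling. Cyclic loess called 1 lower among NRF2 targets and 1 in the integrated stress response. It called 2 lower in the unfolded protein response and 1 among heat shock proteins. For NRF2 targets and antioxidant enzymes, of 37 tested, 5 rose, 8 fell and 24 did not pass (5 higher and 8 lower adjusted over the list alone, 7 and 1 relative to the median change, 8 and 0 with median scaling), and 6 of the falls lay above 0 with median scaling. The glutathione peroxidase gene Gpx1 rose by 2.27 ± 0.25 and Nfe2l2, which encodes NRF2 itself, by 0.44 ± 0.094. Gpx4 fell by 0.50 ± 0.086 and Txnrd2 by 0.54 ± 0.13. In the integrated stress response, of 22 tested, 4 rose, 2 fell and 16 did not pass (4 higher and 2 lower adjusted over the list alone, 5 and 1 relative to the median change, 5 and 0 with median scaling), and 1 of the falls lay above 0 with median scaling. Seryl-tRNA synthetase (Sars1 by 1.30 ± 0.17) and the transcription factor gene Cebpg (Cebpg by 1.13 ± 0.26) rose. The serine synthesis gene Psph and Pck2, which encodes a mitochondrial enzyme, fell (Psph by 0.41 ± 0.11 and Pck2 by 0.63 ± 0.10). For the unfolded protein response of the endoplasmic reticulum, of 16 tested, 3 rose, 6 fell and 7 did not pass (3 higher and 6 lower adjusted over the list alone, 3 and 0 relative to the median change, 4 and 0 with median scaling), and 5 of the falls lay above 0 with median scaling. Pdia3 rose by at least 8.24-fold and Hsp90b1 by 0.94 ± 0.12. Dnajb11 fell by 0.49 ± 0.10 and Herpud1 by 0.49 ± 0.10. For cytosolic heat shock proteins, of 15 tested, 1 rose, 5 fell and 9 did not pass (1 higher and 5 lower adjusted over the list alone, 1 and 1 relative to the median change, 3 and 0 with median scaling), and 4 of the falls lay above 0 with median scaling. Hsp90aa1 rose by at least 6.33-fold, and falls were measured for Dnaja4 by 0.97 ± 0.20, Bag3 by 0.55 ± 0.11 and Dnaja1 by 0.44 ± 0.11. The probe of Cebpg was above background on 3 of the 4 control arrays. Leaving out 1 array at a time changed these counts and calls, with adjusted p in brackets. NRF2 targets had 3 rises without compound 197 replicate 4 and 5 falls without compound 197 replicate 4. The integrated stress response had 2 rises without compound 197 replicate 1. Heat shock proteins had 0 rises without compound 197 replicate 1, 2, 3 or 4 (1 no longer tested), 2 rises without control replicate 3 and 3 falls without compound 197 replicate 3. Psph did not pass without compound 197 replicate 1 (0.0567).

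In the list for muscle atrophy and autophagy, of 26 tested, 4 rose, 5 fell and 17 did not pass (4 higher and 4 lower adjusted over the list alone, 5 and 3 relative to the median change, 5 and 1 with median scaling), and 4 of the falls lay above 0 with median scaling. Rises were found for the lysosomal protease gene Ctsd (4.29 ± 0.12), the autophagy gene Becn1 (2.59 ± 0.14) and the ubiquitin ligase gene Fbxo30 (at least 1.95-fold). Traf6 fell by 1.07 ± 0.15. Among proteasome subunits, of 36 tested, 10 rose, 13 fell and 13 did not pass (10 higher and 14 lower adjusted over the list alone, 12 and 3 relative to the median change, 12 and 0 with median scaling), and 11 of the falls lay above 0 with median scaling. Members with the smallest adjusted p were Psma1 by at least 6.35-fold, Psmc6 by at least 2.34-fold, Psma6 by 1.32 ± 0.11 and Psmc3 by 1.29 ± 0.11, each higher. For cell cycle genes, of 19 tested, 1 rose, 6 fell and 12 did not pass (1 higher and 6 lower adjusted over the list alone, 2 and 0 relative to the median change, 1 and 0 with median scaling), and 4 of the falls lay above 0 with median scaling. Stmn1, a regulator of microtubules, rose by 1.52 ± 0.19. Fen1 fell by 0.56 ± 0.13, Mcm5 by 0.37 ± 0.091 and Cdc20 by 0.41 ± 0.10. In the list of p53 targets and growth arrest, of 11 tested, 3 rose, 2 fell and 6 did not pass (3 higher and 3 lower adjusted over the list alone, 4 and 0 relative to the median change, 4 and 0 with median scaling), and 1 of the falls lay above 0 with median scaling. The cell cycle inhibitor gene Cdkn1b rose by 0.88 ± 0.11, Ccng1 by 0.80 ± 0.10 and Gadd45a by 1.04 ± 0.19. Phlda3 fell by 0.99 ± 0.28. The probe of Ctsd was above background on 1 of the 4 control arrays. The probe of Traf6 was above background on 3 of the 4 compound 197 arrays. The probe of Stmn1 was above background on 1 of the 4 control arrays. These counts and calls changed on leaving out 1 array at a time, with adjusted p in brackets. The cell cycle list had 3 falls without compound 197 replicate 1, 2 or 4. The p53 list had 0 falls without compound 197 replicate 3 or 4 and 1 fall without control replicate 3 or compound 197 replicate 1 or 2. Mcm5 did not pass without compound 197 replicate 4 (0.0601). Cdc20 did not pass without compound 197 replicate 4 (0.0593). Phlda3 did not pass without control replicate 3 (0.0542) or compound 197 replicate 2 (0.0544), 3 (0.0516) or 4 (0.0628).

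Of the lists, fast fibre contractile genes had the smallest p as a set. For fast fibre contractile genes, of 13 tested, 4 rose, 1 fell and 8 did not pass (4 higher and 1 lower adjusted over the list alone, 7 and 0 relative to the median change, 10 and 0 with median scaling), and 1 of the falls lay above 0 with median scaling. The myosin heavy chain genes Myh2 and Myh4 rose by 4.36 ± 0.33 and 3.63 ± 0.26, as did the fast troponin I gene Tnni2 by 1.48 ± 0.12 and the myosin light chain kinase gene Mylk2 by 1.59 ± 0.19. As a set, these genes had a camera p of 0.00128 and an adjusted p = 0.0523, short of the threshold, and adjusted p = 0.935 with an estimated correlation. The list's median change was 0.12 and its mean 0.84. For slow fibre contractile genes, of 12 tested, 0 rose, 1 fell and 11 did not pass (0 higher and 0 lower adjusted over the list alone, 0 and 0 relative to the median change, 0 and 0 with median scaling), and no fall lay above 0 with median scaling. The fall was that of Casq2, by 0.65 ± 0.21. For calcium handling and excitation, of 20 tested, 1 rose, 5 fell and 14 did not pass (1 higher and 1 lower adjusted over the list alone, 3 and 1 relative to the median change, 3 and 0 with median scaling), and 4 of the falls lay above 0 with median scaling. Trdn, a protein of the calcium release complex, rose by 2.02 ± 0.17. Stac3 fell by 0.52 ± 0.10, Fkbp1a by 0.46 ± 0.14 and Stim1 by 0.35 ± 0.11. In the list for muscle regeneration and denervation, of 21 tested, 1 rose, 3 fell and 17 did not pass (1 higher and 3 lower adjusted over the list alone, 1 and 1 relative to the median change, 2 and 0 with median scaling), and no fall lay above 0 with median scaling. Vimentin (Vim) rose by 3.57 ± 0.27. The acetylcholine receptor subunit genes Chrne and Chrnd and the intermediate filament gene Nes fell (Chrne by 1.80 ± 0.49, Chrnd by 1.29 ± 0.37 and Nes by 0.97 ± 0.27). On leaving out 1 array at a time, these counts and calls changed, with adjusted p in brackets. Fast fibre genes had 0 falls without control replicate 1, 2 or 3 or compound 197 replicate 1, 2, 3 or 4. Slow fibre genes had 0 falls without control replicate 1, 3 or 4 or compound 197 replicate 1, 2, 3 or 4. Calcium handling had 3 rises without control replicate 2, 1 fall without control replicate 1 or compound 197 replicate 4, 2 falls without control replicate 4 or compound 197 replicate 1 or 2 and 3 falls without control replicate 3 or compound 197 replicate 3. Regeneration and denervation had 2 rises without control replicate 1, 3 rises without control replicate 2, 1 fall without control replicate 3 or compound 197 replicate 2, 3 or 4 and 5 falls without control replicate 2. Casq2 did not pass without control replicate 1 (0.0925), 3 (0.0889) or 4 (0.0816) or compound 197 replicate 1 (0.0967), 2 (0.0618), 3 (0.0845) or 4 (0.0712). Fkbp1a did not pass without control replicate 1 (0.0535) or compound 197 replicate 1 (0.0878), 3 (0.0685) or 4 (0.0791). Stim1 did not pass without control replicate 1 (0.0533), 3 (0.0697) or 4 (0.0771) or compound 197 replicate 2 (0.0913) or 4 (0.0973). Chrne did not pass without control replicate 1 (0.0516). Nes did not pass without control replicate 3 (0.0544) or compound 197 replicate 2 (0.0534), 3 (0.0597) or 4 (0.0633). Chrnd did not pass without control replicate 3 (0.0582) or compound 197 replicate 2 (0.0576), 3 (0.0518) or 4 (0.0605).

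Among glycolysis and glycogen genes, of 28 tested, 5 rose, 2 fell and 21 did not pass (4 higher and 0 lower adjusted over the list alone, 8 and 0 relative to the median change, 11 and 0 with median scaling), and 1 of the falls lay above 0 with median scaling. The probe of the muscle enolase gene Eno3 rose by 3.66 ± 0.16 (adjusted p = 4.5e-07), that of Eno1 by at least 2.22-fold, and those of Gapdh by 0.87 ± 0.10 and Gyg1 by 0.93 ± 0.12. This list had a camera p of 0.0194 and an adjusted p = 0.397. In creatine and purine nucleotide metabolism, of 17 tested, 2 rose, 2 fell and 13 did not pass (2 higher and 2 lower adjusted over the list alone, 3 and 0 relative to the median change, 5 and 0 with median scaling), and 2 of the falls lay above 0 with median scaling. The AMP deaminase gene Ampd1 rose by 4.05 ± 0.17 and the creatine transporter gene Slc6a8 by 0.38 ± 0.11. Adk fell by 0.57 ± 0.16 and Hprt1 by 0.37 ± 0.11. For lipid synthesis and sterol genes, of 19 tested, 3 rose, 2 fell and 14 did not pass (3 higher and 2 lower adjusted over the list alone, 4 and 0 relative to the median change, 5 and 0 with median scaling), and 1 of the falls lay above 0 with median scaling. The rises were Fdps by 2.23 ± 0.11, Idi1 by 0.82 ± 0.13 and Sc5d by 1.03 ± 0.19. Gpam fell by 0.85 ± 0.22. In the catabolism of branched-chain and other amino acids, of 21 tested, 1 rose, 8 fell and 12 did not pass (1 higher and 8 lower adjusted over the list alone, 2 and 1 relative to the median change, 3 and 0 with median scaling), and 5 of the falls lay above 0 with median scaling. Examples of the falls were Auh by 0.69 ± 0.10, Acat1 by 0.51 ± 0.10, Ivd by 0.64 ± 0.15 and Pccb by 0.55 ± 0.13. For xenobiotic metabolism, of 13 tested, 0 rose, 5 fell and 8 did not pass (0 higher and 5 lower adjusted over the list alone, 0 and 2 relative to the median change, 0 and 0 with median scaling), and 3 of the falls lay above 0 with median scaling. The falls included Aldh1a1 by 0.72 ± 0.14, Fmo2 by 0.95 ± 0.18, Fmo1 by 0.61 ± 0.16 and Por by 0.49 ± 0.13. Leaving out 1 array at a time changed these counts and calls, with adjusted p in brackets. Glycolysis and glycogen had 3 rises without compound 197 replicate 1, 2, 3 or 4 (1 no longer tested), 0 falls without control replicate 3 or compound 197 replicate 1, 2, 3 or 4 and 1 fall without control replicate 1 or 4. Creatine and purine metabolism had 1 rise without control replicate 3 or compound 197 replicate 1, 2 or 3, 0 falls without compound 197 replicate 1, 3 or 4 and 1 fall without control replicate 2 or 4 or compound 197 replicate 2. Lipid and sterol genes had 1 fall without control replicate 1 or compound 197 replicate 2, 3 or 4 and 4 falls without control replicate 2. Amino acid catabolism had 0 rises without control replicate 2, 3 or 4 or compound 197 replicate 1 or 2 and 5 falls without control replicate 1 or compound 197 replicate 2, 3 or 4. Xenobiotic metabolism had 3 falls without compound 197 replicate 4. Adk did not pass without control replicate 1 (0.0602) or compound 197 replicate 1 (0.0507), 3 (0.0522) or 4 (0.0545). Hprt1 did not pass without control replicate 2 (0.0505) or 4 (0.0547) or compound 197 replicate 1 (0.0611), 2 (0.0687), 3 (0.0522) or 4 (0.0831). Slc6a8 did not pass without control replicate 3 (0.0687) or 4 (0.0554) or compound 197 replicate 1 (0.0603), 2 (0.0853) or 3 (0.0767). Fmo1 did not pass without compound 197 replicate 4 (0.0550).

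Lists that can follow the hour or handling of the animals were checked as well. For glucocorticoid-responsive genes, of 12 tested, 2 rose, 1 fell and 9 did not pass (2 higher and 1 lower adjusted over the list alone, 3 and 0 relative to the median change, 3 and 0 with median scaling), and 1 of the falls lay above 0 with median scaling. The rises were Klf15 by 1.27 ± 0.22 and Errfi1 by 1.27 ± 0.24, and Pdk4 fell by 0.44 ± 0.14. For circadian clock genes, of 9 tested, 0 rose, 2 fell and 7 did not pass (0 higher and 2 lower adjusted over the list alone, 1 and 1 relative to the median change, 1 and 0 with median scaling), and no fall lay above 0 with median scaling. The falls were those of Nr1d1 and Bmal1 (Nr1d1 by 1.02 ± 0.25 and Bmal1 by 0.61 ± 0.14). Among immediate early genes, of 19 tested, 1 rose, 4 fell and 14 did not pass (0 higher and 2 lower adjusted over the list alone, 1 and 1 relative to the median change, 3 and 1 with median scaling), and 1 of the falls lay above 0 with median scaling. Atf3 fell by 1.76 ± 0.36, Fos by 0.95 ± 0.28 and Ier2 by 0.83 ± 0.21, and Ier3 rose by 0.35 ± 0.12. In interferon response and antigen presentation, of 22 tested, 3 rose, 5 fell and 14 did not pass (3 higher and 5 lower adjusted over the list alone, 3 and 2 relative to the median change, 4 and 0 with median scaling), and 1 of the falls lay above 0 with median scaling. Psmb9, a subunit of the immunoproteasome, rose by at least 1.14-fold. Stat2 fell by 0.69 ± 0.14, Tapbp by 0.64 ± 0.13 and Irf9 by 0.59 ± 0.12. For inflammation and complement, of 14 tested, 2 rose, 1 fell and 11 did not pass (2 higher and 0 lower adjusted over the list alone, 2 and 0 relative to the median change, 2 and 0 with median scaling), and no fall lay above 0 with median scaling. The complement gene C1s rose by 2.39 ± 0.37 and Vcam1 by 0.74 ± 0.17. Cxcl1 fell by 0.49 ± 0.16. The probe of Vcam1 was above background on 1 of the 4 control arrays. The probe of Cxcl1 was above background on 2 of the 4 compound 197 arrays. These counts and calls changed on leaving out 1 array at a time, with adjusted p in brackets. Glucocorticoid-responsive genes had 0 falls without control replicate 2 or 3 or compound 197 replicate 1, 2 or 4. Immediate early genes had 0 rises without control replicate 1, 3 or 4 or compound 197 replicate 2, 3 or 4, 2 rises without compound 197 replicate 1 and 2 falls without control replicate 2 or compound 197 replicate 1 or 2. The interferon list had 1 rise without compound 197 replicate 1, 3 or 4 (1 no longer tested) and 3 falls without control replicate 3 or compound 197 replicate 1 or 2. Inflammation and complement had 0 falls without control replicate 3 or compound 197 replicate 1, 2, 3 or 4. Pdk4 did not pass without control replicate 2 (0.0580), 3 (0.0703) or 4 (0.0736) or compound 197 replicate 1 (0.0820), 2 (0.0728) or 4 (0.0849). Fos did not pass without control replicate 1 (0.0602), 2 (0.0595) or 3 (0.0618) or compound 197 replicate 1 (0.0747) or 2 (0.0583). Ier3 did not pass without control replicate 1 (0.0754), 2 (0.0889), 3 (0.0586) or 4 (0.0849) or compound 197 replicate 2 (0.0667), 3 (0.123) or 4 (0.123). Cxcl1 did not pass without control replicate 3 (0.0517) or 4 (0.0756) or compound 197 replicate 1 (0.106), 2 (0.102), 3 (0.0738) or 4 (0.0775).

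Markers of the other cell types in a piece of muscle were compared in the same way. For macrophage markers, of 11 tested, 0 rose, 0 fell and 11 did not pass (0 higher and 0 lower adjusted over the list alone, 0 and 0 relative to the median change, 1 and 0 with median scaling). Ctss had a change of 1.13 ± 0.48 with an adjusted p of 0.0911. Mrc1 had a change of -0.60 ± 0.48 with an adjusted p of 0.349. Of the T and B lymphocyte markers, 14 were on the array and 1 passed the detection filter, Ccr7, with the fall given above (0 higher and 1 lower relative to the median change, 0 and 1 with median scaling). Neutrophil and mast cell markers gave 3 genes, of which 1 fell, the mast cell protease gene Cpa3 by 1.17 ± 0.29 (3 lower adjusted over the list alone, 0 higher and 1 lower relative to the median change, 0 and 0 with median scaling). For fibroblast and extracellular matrix markers, of 28 tested, 2 rose, 0 fell and 26 did not pass (1 higher and 0 lower adjusted over the list alone, 2 and 0 relative to the median change, 3 and 0 with median scaling). The microfibril genes Mfap5 and Fbn1 rose by 2.42 ± 0.46 and 1.79 ± 0.48. For endothelial markers, each read by its brightest probe, of 13 tested, 0 rose, 0 fell and 13 did not pass (0 higher and 0 lower adjusted over the list alone, 1 and 0 relative to the median change, 1 and 0 with median scaling). Sox18 had a change of -0.55 ± 0.20 with an adjusted p of 0.0593. Tie1 had a change of -0.54 ± 0.26 with an adjusted p of 0.127. Second probes passed on their own for Cav1, with a change of 0.88 ± 0.16 (adjusted p = 0.00362 over the probes tested), and for Tie1, with -0.59 ± 0.16 (adjusted p = 0.0193). For smooth muscle and pericytes, of 6 tested, 2 rose, 1 fell and 3 did not pass (2 higher and 3 lower adjusted over the list alone, 2 and 0 relative to the median change, 2 and 0 with median scaling), and 1 of the falls lay above 0 with median scaling. Synpo2 rose by 1.85 ± 0.15, Rgs5 by at least 1.08-fold. Smtn fell by 0.44 ± 0.13. Among adipocyte markers, of 12 tested, 1 rose, 0 fell and 11 did not pass (1 higher and 0 lower adjusted over the list alone, 1 and 0 relative to the median change, 2 and 0 with median scaling). The rise was that of Fabp4, by 0.88 ± 0.21. For erythroid and platelet markers, of 6 tested, 0 rose, 0 fell and 6 did not pass (0 higher and 0 lower adjusted over the list alone, 0 and 0 relative to the median change, 0 and 0 with median scaling). Hbb-b1 had a change of 0.64 ± 0.53 with an adjusted p of 0.368. Pf4 had a change of -0.46 ± 0.43 with an adjusted p of 0.423. For Schwann cell and nerve markers, of 7 tested, 0 rose, 3 fell and 4 did not pass (0 higher and 3 lower adjusted over the list alone, 0 and 2 relative to the median change, 0 and 1 with median scaling), and 1 of the falls lay above 0 with median scaling. Falls were measured for Cdh19 by 1.86 ± 0.42, Ngfr by 0.85 ± 0.18 and Nefm by 0.54 ± 0.14. For satellite cells, of 11 tested, 1 rose, 2 fell and 8 did not pass (1 higher and 2 lower adjusted over the list alone, 2 and 0 relative to the median change, 2 and 0 with median scaling), and 1 of the falls lay above 0 with median scaling. Vcam1 rose as given above. Spry1 fell by 0.67 ± 0.18 and Fgfr4 by 0.44 ± 0.11. None of the 7 skin and epithelium markers on the array passed the filter. The probe of Ngfr was above background on 3 of the 4 compound 197 arrays. The probe of Vcam1 was above background on 1 of the 4 control arrays. On leaving out 1 array at a time, these counts and calls changed, with adjusted p in brackets. Macrophage markers had 1 rise without control replicate 2 or compound 197 replicate 2 and 1 fall without control replicate 1 or compound 197 replicate 3. Neutrophil and mast cell markers had 3 falls without control replicate 3. Fibroblast and extracellular matrix markers had 1 rise without compound 197 replicate 4. Endothelium markers had 1 fall without control replicate 1, 2 or 3 and 2 falls without control replicate 4. Smooth muscle and pericyte markers had 1 rise without compound 197 replicate 1, 2, 3 or 4 (1 no longer tested), 0 falls without control replicate 1 or compound 197 replicate 4 and 2 falls without control replicate 2. Adipocyte markers had 2 rises without compound 197 replicate 1 and 1 fall without control replicate 2 or compound 197 replicate 3. Schwann cell and nerve markers had 1 rise without compound 197 replicate 2. Satellite cell markers had 2 rises without control replicate 1 and 1 fall without compound 197 replicate 1 or 3. Ctss passed without control replicate 2 (0.0349). Fbn1 did not pass without compound 197 replicate 4 (0.0556). Sox18 passed without control replicate 1 (0.0461), 2 (0.0463) or 3 (0.0465). Tie1 passed without control replicate 4 (0.0288). Smtn did not pass without control replicate 1 (0.0582) or compound 197 replicate 1 (0.0697) or 4 (0.0667). Nefm did not pass without compound 197 replicate 1 (0.0522). Spry1 did not pass without compound 197 replicate 1 (0.0568) or 3 (0.0547).

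**Figure D4:**
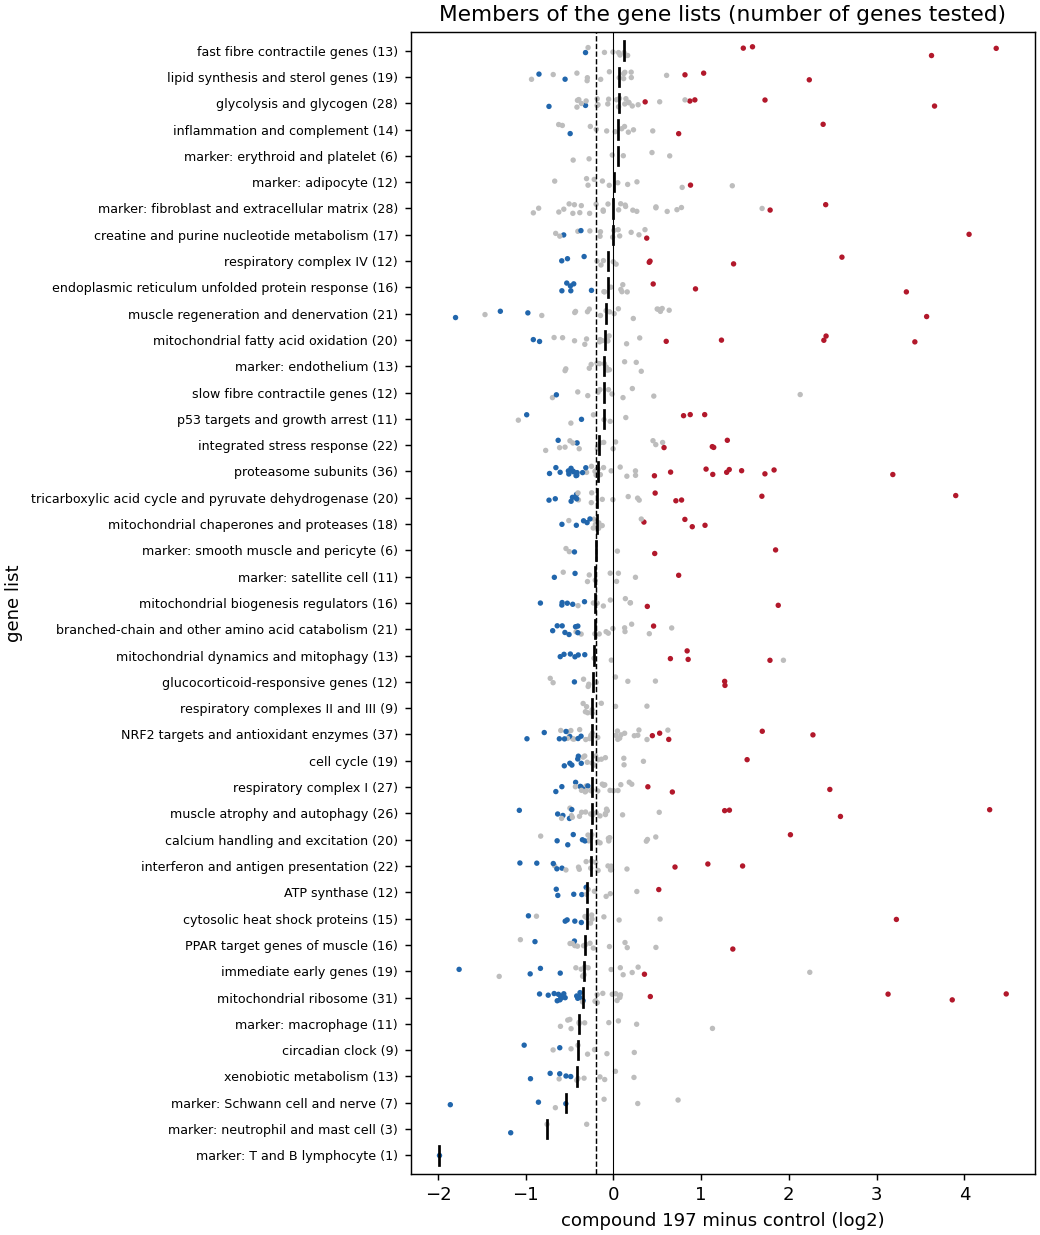
Log2 change, compound 197 minus control, of each tested member of the gene lists, with the number of genes tested in brackets, red points for genes called higher, blue for genes called lower and grey for genes not passing. Black bars are list medians, which were above 0 with median scaling for every list except T and B lymphocytes and neutrophils and mast cells, and the dashed line is the median change of all genes, -0.20.

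Tested as sets with camera at a preset correlation, 0 of 41 lists passed an adjusted p of 0.05, and 2 had an unadjusted p under 0.05, the fast fibre and the glycolysis and glycogen lists. With an estimated correlation, 0 lists passed and 1 had an unadjusted p under 0.05. With fry, which asks whether the genes of a set move on balance 1 way, 3 lists passed, those for fast fibres, glycolysis and glycogen, and proteasome subunits, each with adjusted p = 0.935 in camera with an estimated correlation. In fry's test of change in either direction, 35 lists passed. Neither fry test compares a list with other genes. The fast fibre list passed camera without control replicate 3 (adjusted p = 0.0329) and without compound 197 replicate 1 (0.00710), 2 (0.00690), 3 (0.0242) or 4 (0.00756). On the same arrays, its adjusted p was 0.903 to 0.995 with an estimated correlation. The list for fibroblasts and extracellular matrix, with an adjusted p of 0.730 on all arrays, passed without compound 197 replicate 2 (0.00690), where adjusted p = 0.962 with an estimated correlation. A median below 0 stood beside a mean above 0 for respiratory complex IV, tricarboxylic acid cycle and pyruvate dehydrogenase, mitochondrial fatty acid oxidation, mitochondrial dynamics and mitophagy, mitochondrial ribosome, integrated stress response, endoplasmic reticulum unfolded protein response, muscle atrophy and autophagy, proteasome subunits, slow fibre contractile genes, creatine and purine nucleotide metabolism, glucocorticoid-responsive genes, fibroblast and extracellular matrix markers and smooth muscle and pericyte markers, and those medians were above 0 with median scaling. Across all lists, 703 genes were tested, of which 93 rose and 152 fell, and 96 of the falls lay above 0 with median scaling. Called counts were 146 higher and 4 lower with median scaling and 117 higher and 40 lower with cyclic loess. Relative to the median change, 121 list genes were higher and 41 lower.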

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

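The tests of the second probes, of the raw signals, of the lymphocyte markers and of the shared variation of the falls were chosen after their results had been seen at least in part. The test of the scaling and the other splits of the arrays were chosen before.

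Single arrays stood apart from the other 3 of their group, by Dixon's criterion, for 17 of 326 groups of 4 values examined, or 5.21%, where chance gives about 1 in 20. Rpl30 read 8.45 log2 intensity on compound 197 replicate 3, against 11.91 to 12.14 on the other compound 197 arrays. Among controls, the arrays apart were those of Cox5a on control replicate 2 (13.68 against 13.90 to 13.94), Tomm20 on control replicate 4 (11.01 against 10.80 to 10.83), Gpx4 on control replicate 2 (13.97 against 14.07 to 14.08), Hsp90aa1 on control replicate 4 (5.07 against 4.92 to 4.94) and Psma6 on control replicate 3 (10.84 against 11.19 to 11.20). Further control values apart were Mcm5 on control replicate 1 (5.96 against 5.77 to 5.79), Eno3 on control replicate 3 (9.93 against 10.54 to 10.67), Vcam1 on control replicate 2 (5.78 against 5.38 to 5.45), Mfap5 on control replicate 2 (6.94 against 5.87 to 5.93) and Hbb-b1 on control replicate 4 (9.66 against 10.82 to 11.02). Among compound 197 arrays they were Eloc on compound 197 replicate 4 (9.70 against 9.55 to 9.57), Fndc7 on compound 197 replicate 3 (5.79 against 5.47 to 5.50), Psmc3 on compound 197 replicate 2 (9.31 against 9.03 to 9.06), Mylk2 on compound 197 replicate 4 (12.48 against 12.94 to 13.02), Ier2 on compound 197 replicate 1 (6.57 against 6.20 to 6.25) and Sox18 on compound 197 replicate 2 (6.66 against 6.80 to 6.82).

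Probes that the annotation does not name took no part in the comparison of genes. Tested on their own, 309 of 2572 such probes rose by 1.5 or more on the log2 scale, or 12.01%, against 281 of 7301, or 3.85%, of the named probes (Fisher's exact test, two-sided, p = 6.2e-45, over probes, which are not independent replicates).

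The many-fold rises on the compound 197 arrays were weighed first. A change in transcript level shared by all probes of a gene is argued against for genes with a second tested probe: where 1 probe rose by 1.5 or more, the other had a median change of -0.22 (95% bootstrap interval -0.40 to -0.08, 23 probes). Normalization as their origin is argued against too, since the 261 genes that rose by 1.5 or more had a median change of 1.82 (1.72 to 1.90) in the raw signals. Set against the median change of all genes, the same partner probes differed by -0.024 (-0.20 to 0.12), which restates those values and is no separate test. With no slide named, a technical difference between the groups' arrays that acts probe by probe cannot be told apart from an effect of compound 197 on transcript ends or a sequence difference between the animals under the probes. The lowest raw signal was lower on each compound 197 array (51.1 to 55.5) than on any control array (59.3 to 61.6). Its part in the rises was not tested.

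More genes fell than rose, 65.5% of the calls with quantile normalization. With each array scaled to a common median, falls made up 7.45% of the calls, so the excess of falls may come from the normalization. That scaling has a limit of its own, since 36.9 to 46.6% of probes were above background on an array and the undetected ones set the median, and it does not tell which balance holds in the muscle. A biological excess of falls stays open.

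The largest falls included receptor genes of smell and of lymphocytes. Whether the treated muscle held fewer lymphocytes cannot be decided from their markers. Of the 14 T and B lymphocyte markers on the array, 7.14% passed the detection filter, with Cd3d, Cd3g, Lck and Ms4a1 above background on no array. A fall in markers that are undetected in the controls too cannot be seen. The marker that passed, Ccr7, fell, but it was above background on all 8 arrays, while no other marker was on more than 1. Its signal thus did not go with the other lymphocyte markers, and its fall alone does not show fewer lymphocytes. Ccr7 is also among the 119 falls described next. The 119 genes that fell by 1.2 or more had a mean pairwise correlation of 0.815 between deviations from their group means, against a median of 0.0269 over 1000 sets of smaller falls. Their mean deviation was -0.42, -0.63, 0.65 and 0.40 on control replicates 1 to 4 and -0.18, 0.05, 0.25 and -0.12 on compound 197 replicates 1 to 4, so the shared variation lies mainly between control replicates 1 and 2 and control replicates 3 and 4. A component of the RNA target or background that differs between arrays is consistent with this, and a response to compound 197 on top of it stays open.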

How the results depend on the processing

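Centring, changes relative to the median change and camera on ranks were chosen only after the data were seen. The genes changed by compound 197 numbered 2696, with 931 higher and 1765 lower. Median scaling gave 1490 (111 lower), cyclic loess 1677 (529 lower), changes relative to the median change 1683 (497 lower) and centring on the median of the tested genes 1136 lower. A fold of at least 1.5 left 1386 (667 lower), an adjusted p under 0.01 1325 (646 lower), and a detection p under 0.01 on all 8 arrays 477 higher, with fewer genes tested. The other backgrounds, filters, probe summaries and variance models and the authors' table stayed within 1.5 times. Leaving out 1 array gave 1780 to 2591 genes, 636 to 937 higher and 1144 to 1654 lower, lowest without compound 197 replicate 4 (1780, 1144 lower). The filter stayed at 4 arrays above background, which by itself removes rises detected on the compound 197 arrays alone when 1 of these is left out. Replicate numbers did not pair the arrays, since deviations of same-numbered arrays correlated from -0.181 to -0.048. The replicate block gave 2038 genes, 823 higher and 1215 lower, and 0 lists.

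Gene lists tested as sets numbered 0 past the threshold. That count was 1 with each other background or normalization, the authors' table, no filter, centring and changes relative to the median change, each time for fast fibre contractile genes, and 3 with fry. With an estimated correlation the count was 0 and the fast fibre adjusted p 0.935. Their adjusted p with camera at the preset correlation was 0.00248 with median scaling and 0.0381 with the authors' table, and with fry 6.7e-04. Leaving out 1 array gave 0 to 2 lists, with fast fibres called without control replicate 3 and without each of compound 197 replicates 1 to 4, and fibroblasts and extracellular matrix without compound 197 replicate 2 (0.00690, with adjusted p = 0.962 with an estimated correlation). In every setting that called fast fibres, their adjusted p was 0.702 to 0.995 with an estimated correlation. At the preset correlation, camera also called up to 14 lists in splits of the arrays that mix the groups. Camera on ranks gave 0. Of 160 named genes, 82 kept direction and side of the threshold in every one of the 26 settings that tested them.

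Among named genes, the 31 reversals all came with median scaling, to a change above 0 that did not pass. Genes that had fallen were Ndufb8 (0.16), Atp5mc2 (0.13), Pdk4 (0.16), Fis1 (0.035), Timm23 (0.18), Gpx4 (0.073), Txnrd2 (0.027), Psph (0.15), Dnajb11 (0.096), Herpud1 (0.11), Bag3 (0.069), Dnaja1 (0.15), Fen1 (0.056), Stac3 (0.086), Fkbp1a (0.16), Stim1 (0.27), Acat1 (0.10), Pccb (0.11), Adk (0.0099), Hprt1 (0.25), Por (0.089), Fmo1 (0.050), Irf9 (0.10), Smtn (0.12), Nefm (0.034) and Fgfr4 (0.26). Genes that had not passed before either were Uqcrfs1 (0.26), Mrc1 (0.0066), Sox18 (0.12), Tie1 (0.046) and Pf4 (0.13). Of all genes called, 1063 took the other sign with median scaling (0 passing), 7 with the mean of the probes of a gene (5 passing), 2 with a detection p under 0.01 on all 8 arrays (1 passing), and 1 each with cyclic loess and no filter (0 passing). Which scaling is right was not tested. Signal over background limits the 201 rises read against undetected control probes, and the planned block for the slide was not run, since no slide is named.

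Some lists took the other direction in a set test without passing in it, with adjusted p in brackets. With median scaling these were complex I (0.7503), complexes II and III, calcium handling, macrophage and fibroblast and extracellular matrix (0.862), ATP synthase, biogenesis regulators, mitochondrial ribosome, inflammation and complement and adipocyte (0.879), regeneration and denervation (0.592), slow fibres (0.562) and erythroid and platelet (0.925). With cyclic loess these were complex I, regeneration and denervation, slow fibres and calcium handling (0.979) and macrophage (0.964). With no filter these were atrophy and autophagy (0.944), regeneration and denervation (0.978) and satellite cell (0.920). With centring this was macrophage (0.987). Relative to the median change these were NRF2 targets (0.984), atrophy and autophagy, regeneration and denervation and slow fibres (0.968) and macrophage (0.950). With fry these were mitochondrial chaperones (0.913), NRF2 targets (0.131), integrated stress response (0.275), regeneration and denervation (0.893), slow fibres (0.907), macrophage (0.809), endothelium (0.528) and satellite cell (0.153). With camera on ranks these were dynamics and mitophagy, proteasome subunits and immediate early genes (0.984) and atrophy and autophagy (0.951). On leaving out 1 array at a time these were NRF2 targets (0.723 to 0.978), atrophy and autophagy (0.853 to 0.991), macrophage (0.575 to 0.958), slow fibres (0.535 to 0.946), endothelium (0.792 to 0.978), satellite cell (0.926 to 0.978), immediate early genes (0.769 to 0.934), calcium handling (0.792 to 0.991), the interferon list (0.713 to 0.934) and complex I (0.607 to 0.987), with the lowest and highest adjusted p over the arrays left out.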

Other observations

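The groups of ribosomal and receptor genes and the pairs of probes were chosen only after the data were seen, and the splits of the arrays before. Genes of the cytosolic ribosome, whose proteins are needed in near-equal amounts, differed in their changes: of 60 tested, 20 rose, 16 fell and 24 did not pass, and 13 of the falls lay above 0 with median scaling, which called 21 higher and 2 lower. Their changes ran from -1.79 for Rpl3l, a muscle form of a ribosomal protein, to 4.61 for Rpl30, with an SD of 1.05 across members. Rpl30 read 8.45 on compound 197 replicate 3, against 11.91 to 12.14 on the other compound 197 arrays. The range and the SD include both of these genes. Of 1242 genes for olfactory, vomeronasal and taste receptors on the array, 71 passed the detection filter, of which 1 rose, 23 fell and 47 did not pass, and 1 of the falls lay above 0 with median scaling, which called 2 higher and 15 lower.

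Among genes with 2 tested probes, 8 passed on both probes in 1 direction. Ppid and Med6, a subunit of the Mediator complex, were the 2 that rose, Med6 by 2.00 and 0.58 on probes above background on 1 and 3 control arrays. The 6 that fell were Adamtsl4, Dmtf1, Gtf2ird1, Mettl7a, U2surp and Ubr2. Mettl7a had changes of -1.14 and -1.53, and Adamtsl4 of -1.37 and -0.72.

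The 8 arrays can be split into 4 and 4 in 35 ways, counting mirrors once. Only the real split, 1 of 35, gave as many as 2696 genes, and the highest of the others gave 1. No smaller share than 1 of 35 can be reached, and the other splits mix the groups, which lowers their counts. By the rule fixed before the data were examined, a share of 1 of 35 argues against chance in the grouping as the origin of the gene count. With so few splits, chance is not excluded. A difference in handling that follows the groups is not excluded either. For the lists tested with camera, the real count was 0, which all 35 of 35 splits reach by necessity, so this comparison decides nothing about chance. The other splits gave 0 to 14 lists, most of them more than the real split. Camera at the preset correlation thus called lists under groupings that mix the groups. This limits the fast fibre calls made with it in other settings.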
